A study of Mus musculus with 9 samples.

How the data were processed

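Lungs of 9 mice were profiled by RNA sequencing, with 3 normal mice, 3 mice with a pulmonary fibrosis model and 3 mice given the nanozyme PepNzymeSOD-CAT, and each library was treated as 1 animal. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was selected with oligo(dT) beads, and libraries were made with a buffer that marks the second strand. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm38. The annotation, the counting tool, its strand setting, any filter and all versions upstream are not stated, and neither are the inducer of fibrosis, the dose and the time of sampling. The authors deposited 1 table of FPKM values, in which reads are scaled to transcript length and to library size, with 1 column per library. Column sums ran from 443746 to 519772, so the libraries were not scaled to equal sums. Such sums cannot show whether another scaling between libraries was applied. Read counts were not used here, so the depth of each library and the counting error of each value are unknown, and ratios of low values between libraries showed no steps of whole reads (at most 7.50% of ratios fell in the fullest bin). The library names number the nanozyme libraries apart from the others, and the labels give no date or batch. A separate batch for the nanozyme libraries therefore cannot be told apart from the treatment in either nanozyme comparison.

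The table held 25526 names, of which 21437 matched symbols of GENCODE vM21. A further 3626 entries carry a generic name for new genes, and 1030 of these were tested but not named. Genes entered the tests when FPKM was at least 1 in at least 3 of the 9 libraries, whatever their group, which left 14540. Tests used log2(FPKM + 1) in limma 3.58.1 (R 4.3.3), with all 9 libraries in 1 fit, 1 coefficient per group, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05 within each of 3 comparisons. All tests are two-sided. Figures used matplotlib 3.10.9 and Python 3.11.15. With 3 animals against 3, an exact permutation test of a single gene cannot give a p below 0.10, so no such test was run.

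Before the data were examined, 46 gene lists were fixed: matrix, growth factor and mesenchymal lists, oxidant and antioxidant lists, immune pathways and cell types, lung structural cell types, tissues that could be carried along with lung (blood, cardiac and skeletal muscle, fat), and general programs such as cell cycle, stress, metabolism and clock. Lists with at least 5 tested members, 45 of them, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation for each list. Camera tests whether the mean test statistic of a list's genes is higher or lower than that of the other genes tested. No list call held with the estimated correlation: the count was 0 in each comparison, against 26, 23 and 23 with the preset one. List calls in fits that leave out libraries or change the processing used the preset correlation only. Some lists hold genes expressed by several lung cell types, so a list's direction does not by itself give the number of cells.

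Named genes followed a rule fixed at the same time. Per comparison these are the 12 higher and 12 lower genes with the largest change among those that passed, with a mean FPKM of at least 1, no overlap between groups and a symbol that is not a predicted gene or a receptor segment. Where fewer than 5 passed in a direction, those with the smallest p-values were added up to 5. To these were added Sod1, Sod2, Sod3, Cat, Hmox1, Nqo1, Col1a1, Col3a1, Fn1, Acta2, Tgfb1, Timp1 and Spp1, and per list up to 4 called members with the smallest adjusted p, or 2 members with the highest mean FPKM where 0 were called. The text gives a selection from these, and 2 genes that the rule selects are not reported here.

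Comparisons that share libraries were set against 100 simulated groups with no change and against the overlap of independent lists. Simulated noise was drawn independently for each gene, whereas genes of real libraries vary together. The test was tried on simulated data with 200 changed genes among 14540: at a log2 change of 1 it recovered 64.0%, 61.5% and 67.0% of them for model vs normal, nanozyme vs model and nanozyme vs normal, and at a log2 change of 2 it recovered 94.0%, 94.0% and 96.5%. Changed genes were drawn from those with a mean log2(FPKM + 1) above 1, and all animals of a group shifted alike. The real nanozyme libraries did not stand together, so these shares are not the power of the nanozyme vs model test. Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, equal column sums, median-of-ratios scaling, quantile normalization, rescaling without the 100 most abundant genes, fits of the 2 groups compared, no intensity trend, sample weights, a replicate block, a 2-fold minimum and leaving out each library in turn. Leaving out nanozyme replicate 2 and normal replicate 3 together was chosen after seeing the data. As sample checks, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 9 libraries. Xist, immunoglobulin constant genes and T cell receptor constant genes have no entry and are not analysed here.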

Results

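The data were gene expression values from the lungs of 9 mice in 3 groups of 3: normal mice, mice with a pulmonary fibrosis model, and mice given PepNzymeSOD-CAT, named below as the nanozyme group. A nanozyme is a synthetic material with enzyme-like activity, and this name points to superoxide dismutase, which converts superoxide to hydrogen peroxide, and catalase, which breaks hydrogen peroxide down. The series asked how an inhaled polypeptide nanozyme acts in pulmonary fibrosis. The deposited file held 1 FPKM value per gene and library for 25526 names, of which 14540 were tested. FPKM sums ran from 443746 to 519772 per library. Read counts were not used here, and the depth is therefore unknown. Unless stated otherwise, group values are mean ± SD with n = 3 mice, and changes are log2 fold changes ± SE from limma with Benjamini-Hochberg adjusted p-values.

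The normal libraries differed in composition from the other 6 before any gene was tested. Scgb1a1, the main secretory protein of club cells, held 11.4% to 14.1% of the summed FPKM in the normal libraries and 1.16% to 5.37% in the other 6. The 50 most abundant genes held 33.0% to 35.0% in the normal libraries and at most 27.6% in the others. On the first principal component, which held 62.8% of the variance, the model libraries lay between 39.5 and 61.2 and the normal libraries between -63.5 and -54.8. Nanozyme replicates 1 and 3 lay between them at -14.4 and -9.68, whereas nanozyme replicate 2 lay at 43.3, within the range of the model libraries. Across genes, which are not independent replicates, that library correlated on average at 0.971 with the model libraries and at 0.921 with the other nanozyme libraries.

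**Figure D1:**
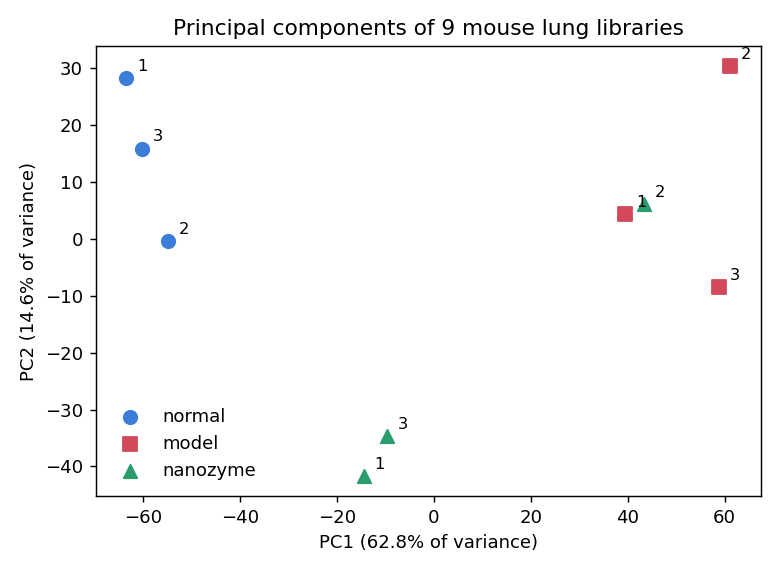
Principal component 1 (horizontal, 62.8% of variance) against component 2 (vertical, 14.6% of variance), in score units, for the 9 lung libraries. Circles are normal, squares model and triangles nanozyme libraries, with replicate numbers beside them, and nanozyme replicate 2 lies at 43.3 on component 1 among the model libraries.

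The first comparison asked what the fibrosis model changed in the lung. By list, camera called cytokine, interferon, neutrophil and cell cycle genes higher and ciliated, club, resident fibroblast and red blood cell genes lower in model lung. None of these calls held with an estimated correlation, for which the smallest adjusted p was 0.483. Saa3, an acute-phase serum amyloid, reached 8921 ± 3729 against 4.97 ± 0.601 FPKM in model and normal lung, respectively (10.47 ± 0.77, adjusted p = 0.000152). S100a8, a subunit of the neutrophil protein calprotectin, was at 1021 ± 187 against 12.4 ± 0.575 FPKM (6.23 ± 0.36, adjusted p = 7.77e-05). Scgb1a1 fell, at 10242 ± 4586 against 63870 ± 7377 FPKM (-2.76 ± 0.41, adjusted p = 0.00195). By limma, 2525 of 14540 tested genes were higher and 3299 lower in model than in normal lung, and 1315 and 1075 of them changed at least 2-fold. At 8499 tested genes (58.5%) the groups did not overlap, where chance gives 10%.

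Acod1, which makes itaconate in activated macrophages, was among the largest rises (8.48 ± 1.22, adjusted p = 0.00177), as was Clec4e, a receptor for microbial and dead-cell lipids (6.79 ± 0.95, adjusted p = 0.00159). The chemokines Cxcl10 (7.27 ± 1.08), Cxcl9 (7.03 ± 1.2) and Ccl3 (6.94 ± 1.18) and the interleukin-1 receptor antagonist Il1rn (6.24 ± 1.09) rose as well, with adjusted p-values from 0.00195 to 0.00360. Ly6i rose by 7.64 ± 1.33, a value that is uncertain because reads can be shared with its close relatives. In the list of inflammatory cytokines and NF-kB targets, 22 of 24 tested members rose and 0 fell (camera adjusted p = 7.11e-11, and adjusted p = 0.538 with an estimated correlation). Its members Il1b, a pyrogenic cytokine, and Ccl2, which attracts monocytes, rose by 5.62 ± 0.78 and 5.04 ± 0.65. In the interferon response list 24 of 25 members rose and 0 fell (camera adjusted p = 3.29e-11, and adjusted p = 0.538 with an estimated correlation), including Irf7, a transcription factor of type I interferon (3.52 ± 0.52). Adjusted over the list alone, 22 members of the cytokine list and 25 of the interferon list were higher and 0 of either lower.

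Some lists of immune cell markers passed and others did not. Of the neutrophil markers, 12 of 13 rose and 0 fell (camera adjusted p = 5.77e-11, and adjusted p = 0.483 with an estimated correlation), including S100a9 (5.97 ± 0.38), Retnlg (5.29 ± 0.3) and the gelatinase Mmp9 (4.42 ± 0.25). Of the monocyte-derived macrophage markers, 18 of 21 rose and 0 fell (camera adjusted p = 4.42e-12, and adjusted p = 0.483 with an estimated correlation), among them the complement genes C1qa (2.55 ± 0.16) and C1qc (2.79 ± 0.14). Of the NK cell markers 8 of 10 rose (camera adjusted p = 2.01e-05, and adjusted p = 0.483 with an estimated correlation), including granzyme gene Gzmb (2.34 ± 0.17). Of the T cell markers 6 of 14 rose (camera adjusted p = 9.43e-05, and adjusted p = 0.538 with an estimated correlation). In MHC class II presentation 8 of 10 rose (camera adjusted p = 0.000551, and adjusted p = 0.483 with an estimated correlation), including the invariant chain gene Cd74 (1.32 ± 0.3). In the type 2 immune response 5 of 13 rose (camera adjusted p = 0.0406, and adjusted p = 0.578 with an estimated correlation), among them the macrophage genes Chil3 (1.78 ± 0.15) and Arg1 (2.99 ± 0.45). Adjusted over the list alone, 12 neutrophil, 19 macrophage, 8 NK cell, 10 T cell, 9 MHC class II and 5 type 2 genes were higher and 0 lower. The lists of alveolar macrophage (4 higher, 2 lower of 14), B cell (1 and 0 of 12), plasma cell (0 and 0 of 7) and dendritic cell markers (2 and 1 of 11) did not pass, with camera adjusted p of 0.370, 0.263, 0.625 and 0.883. Cd209a, a dendritic cell lectin, fell by 2.88 ± 0.14. The mast cell, basophil and eosinophil list had 3 tested members, too few for the test.

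Matrix genes moved in both directions. Among the fibrillar collagens and their processing enzymes 10 of 21 rose and 1 fell (camera adjusted p = 0.00997, and adjusted p = 0.578 with an estimated correlation), with 10 higher and 2 lower adjusted over the list alone. Col1a1 reached 90.7 ± 27.0 against 42.0 ± 1.46 FPKM (1.05 ± 0.22, adjusted p = 0.00665) and Col3a1 299 ± 56.4 against 134 ± 2.24 FPKM (1.13 ± 0.18, adjusted p = 0.00247), and the collagen crosslinking enzyme Lox rose by 1.09 ± 0.18. Of the matrix proteases and inhibitors 15 of 18 rose, also over the list alone, and 0 fell (camera adjusted p = 5.42e-07, and adjusted p = 0.483 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 5.05 ± 0.72 (adjusted p = 0.00170) and the neutrophil collagenase Mmp8 by 5.58 ± 0.37. Fn1, encoding fibronectin (1.5 ± 0.27), Tgfb1 (1.26 ± 0.12) and its induced matrix gene Tgfbi (3.9 ± 0.48) rose, whereas Spp1, encoding osteopontin, did not pass (0.48 ± 0.2, adjusted p = 0.0853). Acta2, the smooth muscle actin of myofibroblasts and vessels, fell from 114 ± 30.1 to 40.2 ± 9.60 FPKM (-1.47 ± 0.25, adjusted p = 0.00333), as did Tagln (-1.91 ± 0.33). The lists of TGF-beta signalling (7 higher, 5 lower of 23), matrix glycoproteins and proteoglycans (4 and 4 of 22), basement membrane (3 and 1 of 19) and myofibroblast markers (2 and 5 of 10) did not pass, with camera adjusted p of 0.420, 0.608, 0.654 and 0.370.

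Genes of oxidant production and defence went different ways. In the GENCODE vM21 annotation of GRCm38, the protein-coding genes Sod1, Sod2 and Cat lie on chromosome 16 from 90220754 to 90226329, chromosome 17 from 13006846 to 13040063 and chromosome 2 from 103453849 to 103485160. Of the NADPH oxidases and phagocyte oxidants 8 of 9 rose and 0 fell, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.45e-06, and adjusted p = 0.483 with an estimated correlation), and Cybb, the catalytic subunit of the phagocyte oxidase, rose by 4.32 ± 0.47. Cat, encoding catalase, fell from 136 ± 10.7 to 55.1 ± 12.9 FPKM (-1.31 ± 0.27, adjusted p = 0.00620). Cytosolic superoxide dismutase Sod1 fell (-0.87 ± 0.18, adjusted p = 0.00705), mitochondrial Sod2 rose (2.5 ± 0.49, adjusted p = 0.00566), and extracellular Sod3 did not pass (-0.24 ± 0.34, adjusted p = 0.595). The haem-degrading enzyme Hmox1 rose (2.79 ± 0.36, adjusted p = 0.00110), as did glutathione reductase Gsr (1.06 ± 0.2), while the glutathione transferase Gstm1 fell (-1.89 ± 0.33) and Nqo1 did not pass (-0.46 ± 0.3, adjusted p = 0.258). The antioxidant enzymes (8 higher, 5 lower of 27) and NRF2 target genes (13 and 7 of 22) did not pass as lists, with camera adjusted p of 0.254 and 0.0748.

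Of 9 lists of structural cells 5 passed as lower and 1 as higher, and 3 did not pass. Of the ciliated cell markers 16 of 18 fell and 0 rose (camera adjusted p = 3.53e-06, and adjusted p = 0.578 with an estimated correlation), among them Tppp3 (-1.7 ± 0.14) and the axonemal dynein gene Dnah11 (-1.58 ± 0.2). Of the club and secretory cell markers 6 of 11 fell (camera adjusted p = 0.0184, and adjusted p = 0.580 with an estimated correlation), including the club cell cytochrome Cyp2f2 (-2.91 ± 0.45). Of the resident fibroblast markers 10 of 17 fell (camera adjusted p = 0.00415, and adjusted p = 0.580 with an estimated correlation), among them Inmt (-2.92 ± 0.67) and the transcription factor Tcf21 (-1.82 ± 0.4). Of the smooth muscle and pericyte markers 8 of 15 fell (camera adjusted p = 0.00493, and adjusted p = 0.578 with an estimated correlation). Of the endothelial markers 8 of 19 fell (camera adjusted p = 0.00415, and adjusted p = 0.603 with an estimated correlation), including Emcn (-0.57 ± 0.11). Adjusted over the list alone, 18 ciliated, 6 club, 11 fibroblast, 8 muscle and 11 endothelial genes were lower and 0 higher. The alveolar type 2 (0 higher, 5 lower of 14) and type 1 (1 and 5 of 12) lists did not pass, with camera adjusted p of 0.0696 and 0.0882. Of their members Sftpc, encoding surfactant protein C (-1.53 ± 0.31), and Hopx (-1.07 ± 0.23) fell and Pdpn rose (1.26 ± 0.15). In the injury-associated transitional epithelium list 5 of 16 rose and 1 fell, also over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.578 with an estimated correlation). Mesothelial markers (1 and 0 of 9) did not pass, with camera adjusted p of 0.264.

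All 28 tested cell cycle genes rose, also over the list alone (camera adjusted p = 4.32e-18, and adjusted p = 0.483 with an estimated correlation), including the proliferation marker Mki67 (2.38 ± 0.19) and the replication helicase gene Mcm5 (2.03 ± 0.13). In glycolysis and hypoxia response 13 of 20 rose and 0 fell (camera adjusted p = 5.28e-05, and adjusted p = 0.514 with an estimated correlation), including pyruvate kinase Pkm (1.54 ± 0.22). In the unfolded protein response 6 of 18 rose and 1 fell (camera adjusted p = 0.0184, and adjusted p = 0.578 with an estimated correlation). In fatty acid oxidation 8 of 16 fell (camera adjusted p = 0.0110, and adjusted p = 0.578 with an estimated correlation), including Acadm (-0.99 ± 0.17). Of the mitochondrially encoded transcripts 8 of 13 fell (camera adjusted p = 0.00301, and adjusted p = 0.578 with an estimated correlation), including mt-Nd2 (-0.96 ± 0.18). In the circadian clock list 7 of 15 fell and 1 rose (camera adjusted p = 0.0430, and adjusted p = 0.578 with an estimated correlation), with the core clock gene Arntl lower (-1.15 ± 0.28). In the heat shock response 6 of 12 fell (camera adjusted p = 0.00918, and adjusted p = 0.538 with an estimated correlation), including Hspa1a (-1.94 ± 0.21). Adjusted over the list alone, the counts of higher and lower genes were 14 and 1 for glycolysis, 6 and 1 for the unfolded protein response, 0 and 9 for fatty acid oxidation, 0 and 8 for mitochondrial transcripts, 1 and 7 for the clock and 0 and 7 for heat shock. The p53, respiratory chain, ribosomal protein and immediate early gene lists did not pass, with camera adjusted p of 0.278, 0.353, 0.340 and 0.858.

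All 6 red blood cell transcripts fell, also over the list alone (camera adjusted p = 0.000582, and adjusted p = 0.538 with an estimated correlation), including Hbb-bs (-4.06 ± 0.55) and Hba-a1 (-4.0 ± 0.54), globin genes with near-identical copies whose single values are uncertain. Of the cardiac muscle transcripts, which pulmonary vein walls also hold in mice, 7 of 11 fell, also over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.603 with an estimated correlation). Other large falls were the esterase gene Pon1 (-3.56 ± 0.75) and the natriuretic peptide receptor gene Npr3 (-2.96 ± 0.54). Skeletal muscle and adipose tissue transcripts did not pass, with camera adjusted p of 0.603 and 0.309. Among lists that did not pass, the median or mean differed in sign from the test for matrix glycoproteins, basement membrane, TGF-beta signalling, alveolar macrophages and dendritic cells.

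Median-of-ratios scaling moved the median change of all tested genes by 0.11 and rescaling without the 100 most abundant genes by -0.11, so that the higher share of the calls went from 43.4% to 53.6% and 32.9%, and to 54.2% with equal column sums. The calls of Scgb1a1 and Sftpc ended with quantile normalization, where the changes shrank to -1.04 and -0.68 (adjusted p = 0.150 and 0.302). They also ended with no filter (0.208 and 0.310), where the changes stayed at -2.76 and -1.53. Spp1 passed with median-of-ratios scaling (0.0438), with only the 2 groups compared (0.0392) and without nanozyme replicate 3 (0.0411). Without normal replicate 1 the counts were 1955 higher and 1987 lower, and without normal replicate 3 they were 1916 and 1920. Without model replicate 2 the calls of the type 2 immune response (adjusted p = 0.0896), transitional epithelium (0.178) and clock (0.0775) lists ended. The type 2 (0.135), transitional epithelium (0.0874) and clock (0.0691) calls also ended without normal replicate 2. The cardiac and clock calls (both 0.0505) ended without model replicate 1, and the club cell (0.0670), cardiac and clock calls (both 0.0556) without model replicate 3. The type 2 call also ended with no filter (0.0703), equal column sums (0.0622), median-of-ratios scaling (0.110) and sample weights (0.0799). The clock and transitional epithelium calls ended with sample weights (0.0609 and 0.0662) and quantile normalization (0.0656 and 0.0735), the clock also without the 100 most abundant genes (0.0856), and the unfolded protein response with quantile normalization (0.178). Without normal replicate 3 the list calls stayed but fewer members were lower: 11 ciliated, 4 resident fibroblast, 2 endothelial and 3 cardiac genes. There were also 3 fatty acid oxidation, 4 mitochondrial, 3 clock and 3 heat shock genes lower, and 3 unfolded protein response and 5 MHC class II genes higher, in that fit. Among lists that did not pass, the higher and lower counts there were 7 and 4 for NRF2 targets, 6 and 3 for antioxidant enzymes, 4 and 2 for TGF-beta signalling, 4 and 1 for matrix glycoproteins and 2 and 3 for myofibroblasts, with 3 alveolar type 2 and 3 type 1 genes lower. The alveolar type 1 list passed as lower without nanozyme replicate 2 (0.0327), also with normal replicate 3 left out as well (0.0367), which was chosen after seeing the data. With all libraries its camera adjusted p was 0.625 with an estimated correlation, which was not run in these fits.

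The second comparison asked what the nanozyme changed in model lung. By limma 0 genes passed in either direction, with 3211 genes at an unadjusted p below 0.05, 1949 of them higher and 1262 lower, and a smallest adjusted p of 0.126. Nanozyme replicates 1 and 3 lay apart from the model libraries and replicate 2 among them, and without replicate 2 1814 genes were higher and 1402 lower than in model lung. Replicate 2 is singled out because it resembles the model libraries, and leaving out such a library raises the calls by construction, so all values without it are conditional on that choice. Leaving out any other library gave at most 1 gene higher and 2 lower. By list, inflammatory, interferon, neutrophil and macrophage genes were lower and B cell, alveolar, endothelial and resident fibroblast genes higher in nanozyme than in model lung by camera. None of these calls held with an estimated correlation, for which the smallest adjusted p was 0.345.

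**Figure D2:**
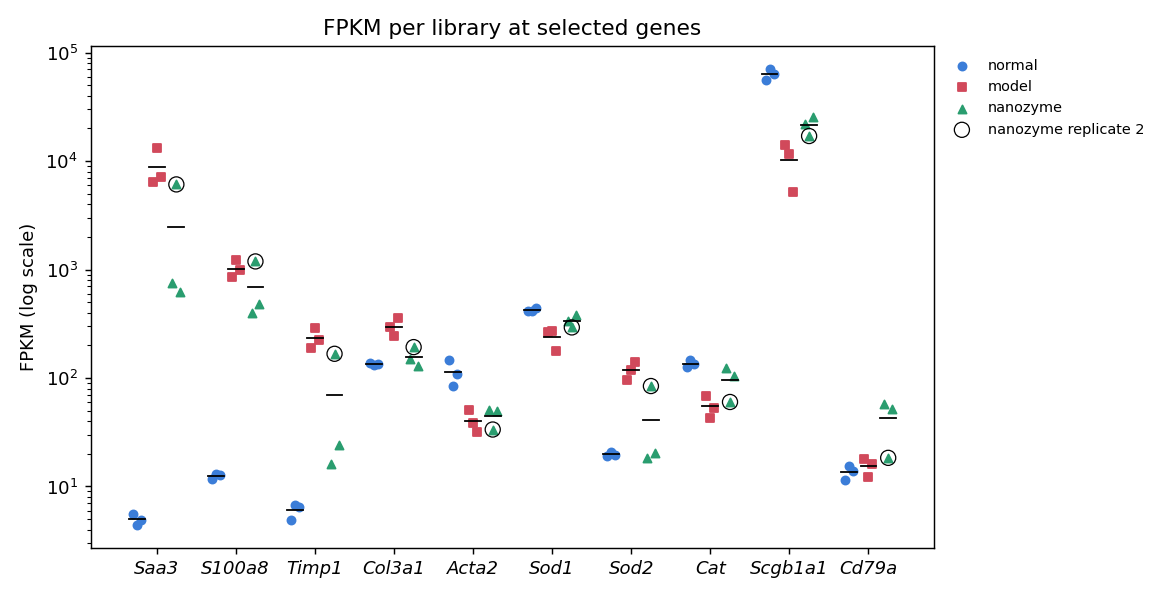
FPKM on a log scale (vertical) at 10 genes (horizontal) in each normal, model and nanozyme library, with a bar at each group mean and a ring around nanozyme replicate 2. At Saa3 the ringed library held 6100 FPKM and nanozyme replicates 1 and 3 held 759 and 619 FPKM.

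Saa3 was at 2493 ± 3125 against 8921 ± 3729 FPKM in nanozyme and model lung (-2.57 ± 0.77, adjusted p = 0.181), and without replicate 2 the change was -3.62, adjusted p = 0.000386. Timp1 was at 69.2 ± 85.1 against 234 ± 50.4 FPKM (-2.47 ± 0.72, adjusted p = 0.181), and at -3.48, adjusted p = 0.000289 without replicate 2. Sod2 stood at -1.85 ± 0.49, adjusted p = 0.181, and at -2.54, adjusted p = 0.000252 without replicate 2. Hmox1 stood at -1.42 ± 0.36, adjusted p = 0.181, and at -1.85, adjusted p = 0.00164 without it. Cat stood at 0.75 ± 0.27, adjusted p = 0.183, and at 1.05, adjusted p = 0.00832 without it. Sod1 (0.52 ± 0.18, adjusted p = 0.182), Sod3 (0.56 ± 0.34, adjusted p = 0.343) and Nqo1 (0.44 ± 0.3, adjusted p = 0.405) passed in neither fit. Of the matrix genes, Col3a1 (-0.92 ± 0.18, adjusted p = 0.181) and Col1a1 (-0.7 ± 0.22, adjusted p = 0.182) passed without replicate 2, at adjusted p of 0.00387 and 0.0484. Fn1 (-0.4 ± 0.27), Acta2 (0.15 ± 0.25), Tgfb1 (-0.27 ± 0.12) and Spp1 (-0.58 ± 0.2) did not, at 0.409, 0.359, 0.111 and 0.0881.

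Genes among those with the smallest p-values in the 9-library fit, given as not passing, were lower for Akr1c14, an aldo-keto reductase (-0.77 ± 0.081, adjusted p = 0.126), Aen, a nuclease induced by p53 (-0.77 ± 0.088), the macrophage gene Ms4a4a (-1.16 ± 0.17), and Tinagl1 (-0.65 ± 0.1). They were higher for the ciliated cell gene Tppp3 (1.04 ± 0.14, adjusted p = 0.178), the calcium-binding S100g (1.28 ± 0.18), Tlcd1 (0.67 ± 0.1), the ribonuclease gene Ear2 (1.06 ± 0.16) and Zfp949 (0.64 ± 0.1). Without replicate 2 all 9 passed, with adjusted p from 0.000371 for S100g to 0.00806 for Tinagl1.

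Several immune lists stood lower in nanozyme lung, while MHC class II presentation did not pass (camera adjusted p = 0.108). Without replicate 2 that list passed at the preset correlation (0.00757, with 6 of 10 lower and 1 higher), and an estimated correlation was not run in that fit. Cytokines and NF-kB targets had a median of -1.98 (camera adjusted p = 6.10e-12, and adjusted p = 0.435 with an estimated correlation), and 0 of its 24 members passed over all genes. Adjusted over the list alone 1 was higher and 19 lower, and without replicate 2 0 were higher and 21 lower. Here and below, counts over the list alone are not adjusted over the lists, and 0 genes passed over all genes with 9 libraries. The interferon response had a median of -1.7 (camera adjusted p = 6.33e-14, and adjusted p = 0.435 with an estimated correlation). Of its members 0 of 25 passed, 23 were lower adjusted over the list alone, and 24 were lower without replicate 2. The interferon-induced GTPase Gbp2 stood at -2.44 ± 0.84. Neutrophil markers had a median of -1.09 (camera adjusted p = 1.73e-07, and adjusted p = 0.415 with an estimated correlation), with 0 of 13, 6 and 10 lower counted the same 3 ways. Its member Lcn2, which binds bacterial iron carriers, stood at -2.54 ± 0.8. Monocyte-derived macrophage markers had a median of -0.66 (camera adjusted p = 6.74e-11, and adjusted p = 0.345 with an estimated correlation), with 0 of 21, 14 and 13 lower. The type 2 immune response was lower (camera adjusted p = 0.000102, and adjusted p = 0.345 with an estimated correlation), with 0 of 13, 3 and 6 lower. Retnla, made by alternatively activated macrophages, stood at -2.15 ± 0.62. NADPH oxidases and phagocyte oxidants were lower (camera adjusted p = 0.000102, and adjusted p = 0.415 with an estimated correlation), with 0 of 9, 7 and 7 lower.

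Some matrix and stress lists were lower as well, whereas matrix glycoproteins, basement membrane and the heat shock response did not pass, with camera adjusted p of 0.565, 0.792 and 0.148. Of these the heat shock response passed as lower without replicate 2 at the preset correlation (0.0343), with 1 of 12 members higher and 0 lower. An estimated correlation was not run in that fit. Matrix proteases and inhibitors had a median of -0.93 (camera adjusted p = 1.44e-08, and adjusted p = 0.345 with an estimated correlation), with 0 of 18 lower over all genes, 12 over the list alone and 14 without replicate 2. The cathepsin gene Ctsb stood at -0.69 ± 0.23. Fibrillar collagens and their processing enzymes had a median of -0.19 (camera adjusted p = 0.000253, and adjusted p = 0.538 with an estimated correlation), with 0 of 21, 2 and 5 lower. Transitional epithelium was lower (camera adjusted p = 4.75e-07, and adjusted p = 0.345 with an estimated correlation), with 0 of 16, 7 and 5 lower. The chaperone gene Clu stood at -0.82 ± 0.18. Glycolysis and hypoxia genes were lower (camera adjusted p = 1.10e-06, and adjusted p = 0.345 with an estimated correlation), with 0 of 20, 9 and 8 lower. NRF2 target genes were lower (camera adjusted p = 0.00573, and adjusted p = 0.579 with an estimated correlation), with 0 of 22, 5 and 9 lower and 0, 3 and 3 higher. The unfolded protein response was lower (camera adjusted p = 0.000174, and adjusted p = 0.435 with an estimated correlation), with 0 of 18, 0 and 10 lower. The chaperone gene Calr stood at -0.6 ± 0.2. The p53 list was lower (camera adjusted p = 0.0302, and adjusted p = 0.345 with an estimated correlation), with 0 of 14 members passing and 3 lower adjusted over the list alone. The cell cycle list had a median of -0.1 (camera adjusted p = 0.0179, and adjusted p = 0.716 with an estimated correlation), with 0 of 28 members passing, also over the list alone.

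In nanozyme lung 9 lists stood higher. B cell markers had a median of 0.99 (camera adjusted p = 0.000253, and adjusted p = 0.555 with an estimated correlation), with 0 of 12 higher over all genes, 11 over the list alone and 11 without replicate 2. Cd79a and Cd79b, the signalling chains of the B cell receptor, stood at 1.27 ± 0.38 and 1.21 ± 0.4. Alveolar type 1 (camera adjusted p = 0.00251, and adjusted p = 0.579 with an estimated correlation) and type 2 (camera adjusted p = 0.00481, and adjusted p = 0.579 with an estimated correlation) markers had 0 of 12 and 0 of 14 higher, 9 and 6 over the list alone, and 9 and 5 without replicate 2. Sftpc was at 18964 ± 5902 against 7851 ± 1465 FPKM (1.24 ± 0.31, adjusted p = 0.181) and Hopx at 0.71 ± 0.23. Resident fibroblast markers had a median of 0.9 (camera adjusted p = 0.000253, and adjusted p = 0.579 with an estimated correlation), with 0 of 17, 3 and 10 higher counted the same 3 ways. Its member Inmt stood at 2.33 ± 0.67. Endothelial markers (camera adjusted p = 3.50e-05, and adjusted p = 0.579 with an estimated correlation) had 0 of 19, 3 and 9 higher. Alveolar macrophage markers (camera adjusted p = 0.00167, and adjusted p = 0.345 with an estimated correlation) had 0 of 14, 7 and 7 higher. The circadian clock (camera adjusted p = 0.00528, and adjusted p = 0.538 with an estimated correlation) had 0 of 15, 8 and 9 higher, with the clock output genes Nr1d1 and Tef at 1.93 ± 0.47 and 1.46 ± 0.33. Fatty acid oxidation was higher (camera adjusted p = 0.0305, and adjusted p = 0.651 with an estimated correlation), with 0 of 16, 0 and 3 higher. Ribosomal proteins were higher (camera adjusted p = 0.0119, and adjusted p = 0.798 with an estimated correlation), with 0 of 32, 0 and 0 higher. Ciliated, club cell, smooth muscle, mesothelial and plasma cell markers did not pass, with camera adjusted p of 0.416, 0.248, 0.0522, 0.454 and 0.0673. The last 3 passed as higher without replicate 2 (0.0176, 0.00688 and 0.00710), with 3, 4 and 5 members higher. These calls used the preset correlation, and an estimated one was not run in that fit. In the 9-library fit Scgb1a1 stood at 1.17 ± 0.41, adjusted p = 0.182. Antioxidant enzymes (0.160), TGF-beta signalling (0.145) and myofibroblast markers (0.807) did not pass either. Members in the direction opposite to their list, over the list alone and without replicate 2, were 1 and 1 for phagocyte oxidants, type 2 immunity, the p53 list, clock and alveolar type 1, and 1 and 0 for cytokines. They were 0 and 1 for alveolar type 2, alveolar macrophages, B cells, fibrillar collagens, matrix proteases and the unfolded protein response. The median or mean differed in sign from the test for matrix glycoproteins, TGF-beta signalling, myofibroblasts, T cells, club cells, cardiac and adipose transcripts, respiratory chain and immediate early genes, which did not pass.

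With sample weights in limma, which gave nanozyme replicate 2 a weight of 0.191, 1662 genes were higher and 1372 lower. With these weights all named genes that passed without replicate 2 passed, as did Sod1 (0.0232), Tgfb1 (0.0362), Spp1 (0.0360) and Scgb1a1 (0.0338). With no filter Akr1c14 passed (0.0375) in the 9-library fit. Gene counts were 1081 higher and 1132 lower without nanozyme replicate 2 and normal replicate 3, an alternative chosen after seeing the data. The cell cycle call ended without nanozyme replicate 3 (adjusted p = 0.80) or model replicate 3 (0.0829). The fatty acid oxidation call ended without nanozyme replicate 1 (0.0621), nanozyme replicate 3 (0.0556), model replicate 1 (0.0689) or model replicate 3 (0.194). The ribosomal protein call ended without model replicate 1 (0.441) or 3 (0.331), the p53 call without model replicate 1 (0.0548), and the NRF2 call without model replicate 2 (0.0698). The p53 call also ended with no filter (0.0979), median-of-ratios scaling (0.0607) and quantile normalization (0.0904), and the NRF2 call with quantile normalization (0.0567). The cell cycle call ended with the filter at a mean FPKM of 5 (0.0918) and the fatty acid oxidation call with median-of-ratios scaling (0.0778). The ribosomal protein call ended with that scaling (0.0768) and without nanozyme replicate 2 and normal replicate 3 together (0.0538).

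**Figure D3:**
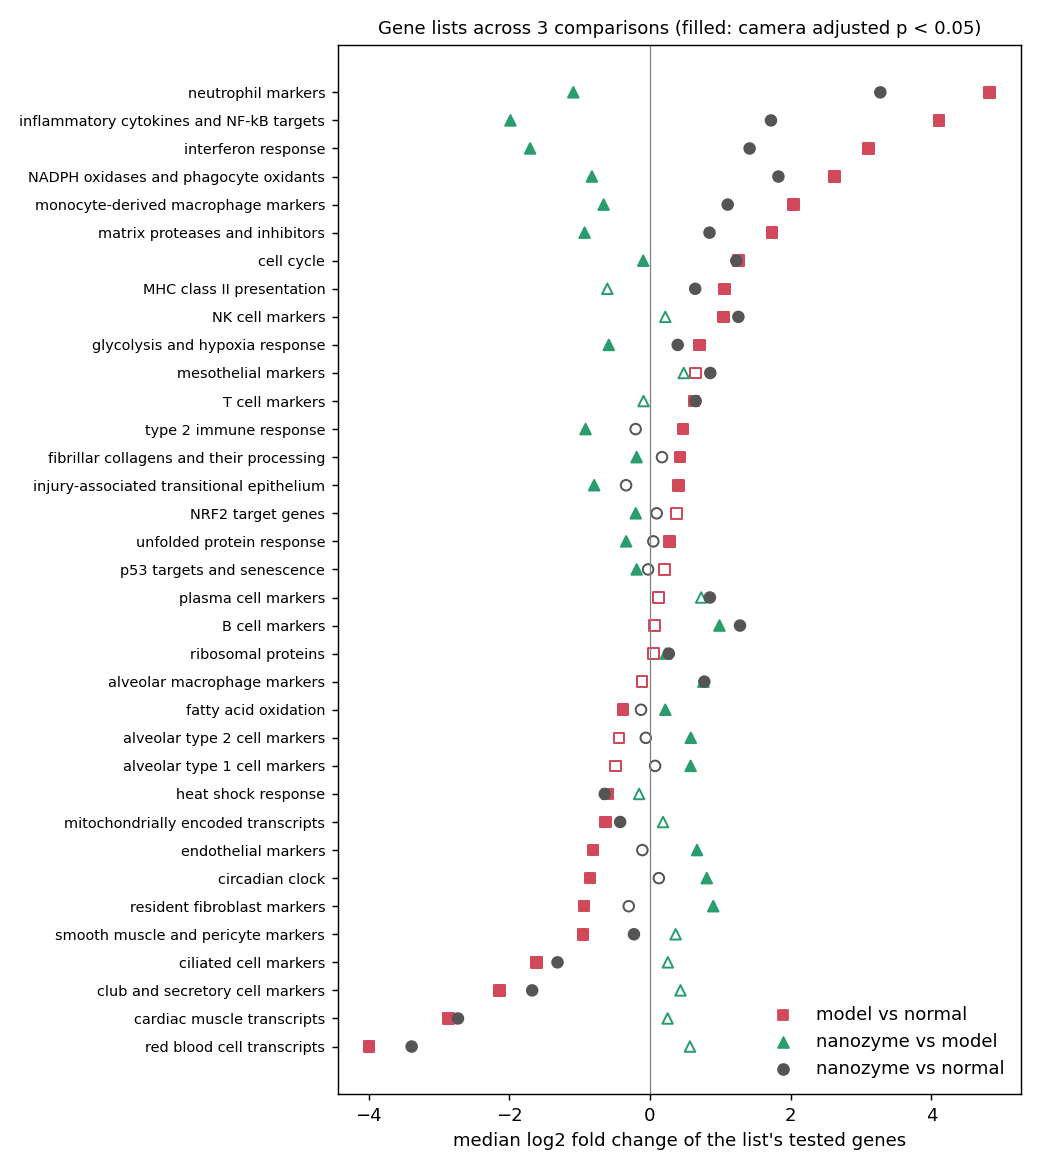
Median log2 fold change (horizontal) of the tested genes of each gene list that passed camera in at least 1 comparison (vertical). Squares are model vs normal, triangles nanozyme vs model and circles nanozyme vs normal, filled where the camera adjusted p was below 0.05, and neutrophil markers stand at 4.83, -1.09 and 3.28.

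The third comparison asked how far nanozyme lungs lay from normal lungs. By list, camera called neutrophil, macrophage, cell cycle and lymphocyte genes higher than in normal lung, and ciliated, club cell, heat shock and red blood cell genes lower. None of these calls held with an estimated correlation, for which the smallest adjusted p was 0.272. S100a8 was at 690 ± 434 against 12.4 ± 0.575 FPKM in nanozyme and normal lung (5.51 ± 0.36, adjusted p = 0.000251), and Saa3 at 2493 ± 3125 against 4.97 ± 0.601 FPKM (7.9 ± 0.77, adjusted p = 0.000853). By limma 1220 genes were higher and 800 lower, and 647 and 306 of them changed at least 2-fold. At 6242 tested genes (42.9%) the groups did not overlap, where chance gives 10%.

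Of the neutrophil markers 11 of 13 rose and 0 fell (camera adjusted p = 5.46e-11, and adjusted p = 0.342 with an estimated correlation), among them S100a9 (5.2 ± 0.38), Retnlg (4.89 ± 0.3) and Mmp9 (3.28 ± 0.25). Other large rises were Stfa2l1, a stefin-like protease inhibitor gene (4.29 ± 0.24), the protease gene Asprv1 (4.7 ± 0.57), Wfdc17 (4.06 ± 0.44) and complement factor B gene Cfb (4.04 ± 0.58). Of the monocyte-derived macrophage markers 12 of 21 rose (camera adjusted p = 6.63e-10, and adjusted p = 0.365 with an estimated correlation), including C1qc (2.38 ± 0.14) and Adgre1 (2.97 ± 0.24). Of the alveolar macrophage markers 7 of 14 rose (camera adjusted p = 0.000312, and adjusted p = 0.272 with an estimated correlation), including the scavenger receptor Marco (2.94 ± 0.35), Ear2 (1.09 ± 0.16) and Chil3 (1.75 ± 0.15). Phagocyte oxidant genes had 6 of 9 higher (camera adjusted p = 9.45e-06, and adjusted p = 0.365 with an estimated correlation), and cytokines 5 of 24 (camera adjusted p = 5.12e-06, and adjusted p = 0.622 with an estimated correlation). The interferon response had 2 of 25 higher (camera adjusted p = 1.83e-05, and adjusted p = 0.690 with an estimated correlation) and MHC class II presentation 2 of 10 (camera adjusted p = 0.000807, and adjusted p = 0.434 with an estimated correlation). NK cell markers had 8 of 10 higher (camera adjusted p = 2.04e-09, and adjusted p = 0.336 with an estimated correlation), including perforin Prf1 (1.81 ± 0.13) and Gzmb (2.34 ± 0.17). T cell markers had 5 of 14 higher (camera adjusted p = 2.26e-05, and adjusted p = 0.470 with an estimated correlation). B cell markers had 5 of 12 higher (camera adjusted p = 9.45e-06, and adjusted p = 0.470 with an estimated correlation), including Cd22 (1.74 ± 0.28) and Fcer2a (1.49 ± 0.19). Plasma cell markers had 1 of 7 higher (camera adjusted p = 0.0483, and adjusted p = 0.690 with an estimated correlation). Adjusted over the list alone, 12 neutrophil, 13 macrophage, 9 alveolar macrophage, 7 oxidant, 13 cytokine, 0 interferon, 3 MHC class II, 10 NK cell, 9 T cell, 11 B cell and 4 plasma cell genes were higher.

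Of the cell cycle genes 26 of 28 rose (camera adjusted p = 7.75e-23, and adjusted p = 0.336 with an estimated correlation), or 28 over the list alone, including Birc5 (2.26 ± 0.15) and Mcm5 (1.93 ± 0.13). Matrix proteases and inhibitors had 7 of 18 higher, or 9 over the list alone (camera adjusted p = 0.000307, and adjusted p = 0.556 with an estimated correlation), including Mmp8 (3.88 ± 0.37) and Timp1 (2.58 ± 0.72, adjusted p = 0.0485). Fn1 (1.1 ± 0.27, adjusted p = 0.0321), Tgfb1 (0.99 ± 0.12, adjusted p = 0.00213) and Hmox1 (1.37 ± 0.36, adjusted p = 0.0384) rose and Acta2 fell (-1.31 ± 0.25, adjusted p = 0.0127). Col1a1 (0.35 ± 0.22, adjusted p = 0.319), Col3a1 (0.21 ± 0.18, adjusted p = 0.483), Spp1 (-0.1 ± 0.2), Cat (-0.56 ± 0.27, adjusted p = 0.193), Sod1 (-0.35 ± 0.18, adjusted p = 0.237), Sod2 (0.65 ± 0.49, adjusted p = 0.421), Sod3 (0.32 ± 0.34) and Nqo1 (-0.015 ± 0.3) did not pass. The fibrillar collagen, antioxidant enzyme and NRF2 lists did not pass, with camera adjusted p of 0.320, 0.617 and 0.636. Glycolysis genes were higher (camera adjusted p = 0.0406, and adjusted p = 0.690 with an estimated correlation), with 2 of 20 passing, also over the list alone. Mesothelial markers were higher (camera adjusted p = 0.0451, and adjusted p = 0.799 with an estimated correlation), with 0 of 9 passing, also over the list alone. Single libraries stood apart in tissue carried along with lung: skeletal muscle transcripts had a median of 5.02 above the normal mean in nanozyme replicate 1 and 3.53 in model replicate 2, against -0.83 to -0.36 in the other model and nanozyme libraries. Nanozyme replicate 1 also had the highest adipose level of its group (0.34, against -1.70 and -2.17) and the highest mesothelial (1.75), plasma cell (1.58) and B cell (1.78) levels of all 9 libraries. Ribosomal proteins were higher (camera adjusted p = 0.000859, and adjusted p = 0.799 with an estimated correlation), with 1 of 32 passing and 0 over the list alone.

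Of the ciliated cell markers 10 of 18 fell (camera adjusted p = 8.43e-10, and adjusted p = 0.470 with an estimated correlation), or 18 over the list alone, including Dnah11 (-1.36 ± 0.2). Of the club and secretory markers 3 of 11 fell, also over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.622 with an estimated correlation), including Aldh1a7 (-1.21 ± 0.14) and Scgb1a1, at 21535 ± 4360 against 63870 ± 7377 FPKM (-1.58 ± 0.41, adjusted p = 0.0373). In the heat shock response 5 of 12 fell, or 8 over the list alone (camera adjusted p = 2.53e-05, and adjusted p = 0.342 with an estimated correlation), including the inducible chaperones Hspa1b (-2.37 ± 0.27) and Hspa1a (-2.09 ± 0.21), which are near-identical copies and therefore uncertain singly. Red blood cell transcripts had 5 of 6 lower, or 6 over the list alone (camera adjusted p = 2.26e-05, and adjusted p = 0.434 with an estimated correlation), with Hbb-bs at -3.51 ± 0.55 and Hba-a1 at -3.38 ± 0.54. Cardiac muscle transcripts had 3 of 11 lower, or 7 over the list alone (camera adjusted p = 0.000807, and adjusted p = 0.665 with an estimated correlation). They included the cardiac myosin Myh6 (-3.41 ± 0.78, adjusted p = 0.0243). Smooth muscle markers had 3 of 15 lower, or 5 over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.690 with an estimated correlation). Mitochondrially encoded transcripts had 2 of 13 lower, or 3 (camera adjusted p = 0.000458, and adjusted p = 0.622 with an estimated correlation). The dendritic cell genes Cd209a (-2.63 ± 0.14) and Ccl17, a chemokine (-1.85 ± 0.46, adjusted p = 0.0317), fell. The clock genes Npas2 (-1.69 ± 0.19) and Bhlhe41 (1.31 ± 0.15) fell and rose in a clock list that did not pass (0.891). The endothelial, resident fibroblast, alveolar type 1, alveolar type 2 and transitional epithelium lists did not pass, with camera adjusted p of 0.636, 0.266, 0.726, 0.846 and 0.636. The median or mean differed in sign from the test for matrix glycoproteins, TGF-beta signalling, the type 2 immune response, dendritic cells and the clock, which did not pass.

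Rescaling moved the higher share of these calls from 60.4% to 70.4% with equal column sums, 46.8% with quantile normalization and 47.3% without the 100 most abundant genes. Without normal replicate 3 600 genes were higher and 148 lower, and without normal replicate 1 627 and 168. Leaving out each of these in turn ended the calls of Acta2 (adjusted p = 0.0524 without replicate 3 and 0.0514 without replicate 1), Ccl17 (0.0991 and 0.0902), Fn1 (0.101 and 0.105), Hmox1 (0.115 and 0.131), Myh6 (0.0830 and 0.0983), Scgb1a1 (0.122 and 0.102) and Timp1 (0.127 and 0.151). With quantile normalization, which gives the top rank 1 value in every library, Scgb1a1 stood at 0, and with no filter its call ended (0.558). The lower count was 435 without nanozyme replicate 1 and 474 without nanozyme replicate 3. Fn1 also missed the threshold without nanozyme replicate 1 (0.0839), nanozyme replicate 2 (0.0590), model replicate 1 (0.0502) or normal replicate 2 (0.0758). Hmox1 missed it without nanozyme replicate 1 (0.0578), model replicate 1 (0.0528), model replicate 3 (0.0551) or normal replicate 2 (0.0723), and Scgb1a1 missed it without nanozyme replicate 1 (0.0834), 2 (0.0807) or 3 (0.0648) or normal replicate 2 (0.103). Myh6 missed it without nanozyme replicate 2 (0.0570) or 3 (0.0693), Ccl17 without nanozyme replicate 3 (0.0690) or normal replicate 2 (0.0819). Timp1 missed it without nanozyme replicate 3 (0.0606), model replicate 1 (0.0698), 2 (0.0633) or 3 (0.0691) or normal replicate 2 (0.0953). The call of Timp1 also ended with no filter (0.0740), the filter at a mean FPKM of 5 (0.0540), median-of-ratios scaling (0.0536) and only the 2 groups compared (0.0935). That of Hmox1 ended with no filter (0.0595) and the 2 groups (0.0625), and that of Fn1 with rescaling without the 100 most abundant genes (0.0505). Ccl17 missed it with no filter (0.0514), the 2 groups (0.0619) and the replicate block (0.0531), and Scgb1a1 with the replicate block (0.0679). Without nanozyme replicate 2 and normal replicate 3 together, an alternative chosen after seeing the data, Acta2 (0.0813), Fn1 (0.145), Hmox1 (0.103), Myh6 (0.140) and Scgb1a1 (0.202) did not pass. Cat passed with sample weights (0.0488). Among the lists, smooth muscle and glycolysis calls ended without nanozyme replicate 2 (0.116 and 0.229), glycolysis also without model replicate 2 (0.0503) or normal replicate 2 (0.105). The mesothelial call ended without nanozyme replicate 1 (0.291) or 3 (0.131), model replicate 1 (0.0553) or 2 (0.0527) or normal replicate 1 (0.0840). The plasma cell call ended without nanozyme replicate 1 (0.102) or 3 (0.0837), any model replicate (0.0575, 0.0763 and 0.0610) or normal replicate 1 (0.0745) or 2 (0.0502). The plasma cell and mesothelial calls also ended with a pseudocount of 0.1 (0.0512 and 0.0516), equal column sums (0.0732 and 0.0812) and only the 2 groups compared (0.0992 and 0.0628). With the filter at a mean FPKM of 5 the mesothelial (0.105) and glycolysis (0.0964) calls ended and the plasma cell list was not tested. Glycolysis also ended with median-of-ratios scaling (0.0568), and glycolysis and smooth muscle with sample weights (0.224 and 0.0710) and without nanozyme replicate 2 and normal replicate 3 together (0.244 and 0.0986). Counts of list members moved with single libraries. Without nanozyme replicate 2, 10 cytokine, 7 interferon, 4 MHC class II, 12 B cell, 5 plasma cell and 6 mesothelial genes were higher, and 8 heat shock, 1 smooth muscle, 1 mitochondrial and 0 cardiac genes lower. Without normal replicate 3, 1 cytokine, 0 interferon, 2 B cell, 3 T cell, 0 plasma cell, 2 matrix protease, 0 glycolysis and 0 ribosomal protein genes were higher. In that fit 4 ciliated, 1 club cell, 3 heat shock, 0 cardiac, 0 smooth muscle and 0 mitochondrial genes were lower.

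Changes from normal lung were compared between the model and nanozyme groups. Of the genes higher than in normal lung, 1124 were called in both groups, where independent lists of 2525 and 1220 genes would share 212, and of the lower genes 769, where lists of 3299 and 800 would share 182. In 100 draws all libraries, the normal ones included, were simulated around the normal means with no change in any group, and at most 1 call was shared. Hardly any gene is called without a change, so this does not show how much overlap shared normal libraries create between changed groups. The noise was also drawn independently for each gene. Across genes the log2 fold changes had a covariance of 0.52, against 0.033 simulated, and a correlation of 0.87, against 0.50. The 3 normal libraries cannot be divided into parts of at least 2, so part of the excess may come from the shared normal libraries. In the nanozyme group 96 genes were called higher and 31 lower that were not called in model lung, a difference between groups that was not itself tested for these genes.

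Genes changed in the model were then followed into the nanozyme group. By limma 0 of the 5824 genes called between model and normal were also called in the opposite direction between nanozyme and model. Without nanozyme replicate 2 there were 2645 such genes, and 46 were called in the same direction. Of the 2754 genes higher in model lung in that fit, 1314 were lower in nanozyme lung, where independent lists would share 266, and of 3836 lower genes 1331 were higher, where independent lists would share 479. Because the model libraries enter both comparisons, opposite signs also arise by chance. With all 9 libraries 92.8% of the called genes had opposite signs, against 57.1% (range 55.3% to 59.1%) in 100 simulated groups drawn around the model means, and the covariance was -0.36 against -0.034. Without nanozyme replicate 2 these were 91.6% against 55.3% and -0.49 against -0.025, and part of the excess may come from the shared model libraries, which cannot be divided into parts of at least 2. The simulated noise was independent for each gene, whereas genes of real libraries vary together. The simulated range therefore does not measure chance for such genes, and the excess does not by itself show a reversal. The 16 gene lists that camera called in both comparisons had opposite directions, which the shared model libraries favour and which was not set against simulated lists, and none of the 16 held with an estimated correlation. On a scale set at 0 by the model mean and at 1 by the normal mean, over the 2390 genes called with at least a 2-fold change between these groups, nanozyme replicates 1, 2 and 3 had median positions of 0.52, 0.12 and 0.55. Single model libraries lay at 0.17, -0.081 and -0.070 and normal libraries at 1.03, 0.97 and 1.0, each left out of its own group's mean. The genes were chosen with these same libraries, which draws them towards 0 and 1. They are therefore not a fair reference for the nanozyme libraries, which took no part in the choice.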

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

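All alternatives were planned before the data were examined except leaving out nanozyme replicate 2 and normal replicate 3 together, which was chosen after seeing the data. Counts under alternatives not given here stayed within 1.5 times those reported. With an estimated correlation between genes, 0 gene lists passed in each comparison. With a 2-fold minimum the model vs normal counts were 1315 higher and 1075 lower, and the nanozyme vs normal counts 647 and 306. With the filter at a mean FPKM of 5, which tests fewer genes, 2152 genes were lower in model than normal, and 807 were higher and 478 lower in nanozyme than normal. With no filter, 1 gene was higher and 3 lower in nanozyme than model, and 3 had moved back. Quantile normalization gave 1306 genes lower in nanozyme than normal. With sample weights, 1662 genes were higher and 1372 lower in nanozyme than model, 3164 and 2581 in nanozyme than normal, and 2587 had moved back. These weights gave nanozyme replicate 2 0.191, model replicate 2 0.249 and normal replicate 3 12.3, so this alternative leans on the last. Without nanozyme replicate 2 and normal replicate 3, the same counts were 1081 and 1132, 765 and 114, and 1791. The cause of these shifts was not tested.

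When each library was left out in turn, counts ran from 1916 to 2754 (higher) and from 1920 to 3836 (lower) for model vs normal. They ran from 0 to 1814 and from 0 to 1402 for nanozyme vs model, from 600 to 1353 and from 148 to 917 for nanozyme vs normal, and from 0 to 2645 for genes moved back. The highest nanozyme vs model and moved-back counts came without nanozyme replicate 2, and the lowest nanozyme vs normal counts without normal replicate 3. Gene lists that passed ran from 23 to 29, 21 to 28 and 20 to 23 in the 3 comparisons.

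No clear pairing of the libraries by replicate number was seen. Over 9 same-numbered pairs from different groups the correlation of deviations ran from -0.331 to 0.227, over 0.1 in 2. Of the 9, 2 correlated best with their own number. Model and nanozyme pairs stood at 0.086, 0.227 and 0.135, normal and model pairs at -0.0080, -0.331 and -0.112, and normal and nanozyme pairs at 0.058, -0.029 and -0.031. Deviations from means of 3 libraries are a weak check, which cannot exclude pairing. With the replicate number as a block the counts were 2402 and 3226, 0 and 0, and 1117 and 617, with 26, 25 and 24 lists and 0 genes moved back.

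Of the named genes, 1311 of 1320 values under the alternatives for model vs normal, 683 of 775 for nanozyme vs model and 899 of 962 for nanozyme vs normal kept their direction and their side of the threshold. Signs turned only at genes that did not pass. Acta2 in nanozyme vs model ran from -0.0045 (without model replicate 3) to 0.35 over the left-out libraries. In nanozyme vs normal, Nqo1 ran from -0.30 to 0.19 over the left-out libraries, and stood at 0.037 with equal column sums, 0.027 with sample weights and 0.18 without both libraries. Sod2 ran from -0.040 to 1.03, and stood at -0.047 without both, and Spp1 ran from -0.26 to 0.10. In model vs normal, Sod3 ran from -0.46 to 0.18, and stood at 0.022 with sample weights. The cause was not tested. Unknown depth limits what low FPKM values can show.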

Other observations

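The tests of nanozyme replicate 2, normal replicate 3 and the structural markers were chosen only after the results were seen, and the tests of symbol families and of other splits were fixed before their results were seen. Genes were also grouped by the letters their symbols share, over 237 families with at least 8 tested members. In model vs normal, 16 families held more higher genes than other tested genes did and 7 more lower genes (Fisher's exact test with Benjamini-Hochberg adjustment), so that the families did not change only as often as other genes. All 10 tested Gbp genes, interferon-induced GTPases, were higher (adjusted p = 1.46e-06), as were 13 of 15 Ifi genes (7.44e-07), 9 of 11 Toll-like receptor genes (0.000220) and all 8 Csf genes, colony-stimulating factors and their receptors (3.88e-05). Of the Mcm family, which holds the replication helicase subunits, 7 of 10 were higher (0.00633). All 11 tested Dnah genes, axonemal dynein heavy chains, were lower (6.40e-06), as were 26 of 31 Cfap genes of cilia and flagella (1.96e-10) and 10 of 14 intraflagellar transport genes (0.00678). In nanozyme vs normal, all 11 Dnah genes (1.55e-12) and 20 of 31 Cfap genes (5.81e-16) were lower and 7 of 8 Klra genes, NK cell receptors, were higher (1.69e-05). Gbp, Ifi and Klra genes have close relatives that can share reads, so single members are uncertain. Members of a family are not independent, which these p-values do not take into account.

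In each comparison the 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. For genes higher and lower in model than normal, 1 split each, the real one, gave as many as 2525 and 3299, and the highest of the others was 1 in both directions. For nanozyme vs normal 1 split each gave as many as 1220 and 800, and the highest other was 2. For nanozyme vs model the real counts were 0, so all 10 splits gave at least as many by construction, also for the 0 genes moved back. These splits therefore say nothing about that comparison, and the highest others were 3 for genes called and 3 for genes moved back. For genes called, a highest other is the larger of the higher and lower counts, because a mirrored split swaps them. Gene lists are less specific to the real split: 4, 3 and 3 splits gave as many lists as the real 26, 23 and 23, and the highest others were 27, 24 and 24.

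Nanozyme replicate 2 stood with the model libraries at most genes. Labels swapped with a model library were asked about first, and 0 model libraries correlated better with nanozyme replicates 1 and 3 than with the other model libraries. That argues against a swap only for an animal that responded like those replicates. For an animal that responded less it cannot decide: model replicate 1 correlated on average at 0.925 with nanozyme replicates 1 and 3, and nanozyme replicate 2 at 0.921. Each model library was in turn kept out of the choice of genes where nanozyme replicates 1 and 3 lay outside the others (182 to 208 genes), and from model (0) to those replicates (1) nanozyme replicate 2 had median positions of 0.13, 0.068 and 0.12, against 0.11, -0.11 and 0.17 for the library kept out. The smallest difference was -0.0499, so a model library under a nanozyme label cannot be told apart, with 3 libraries to set the range, though alveolar macrophage markers, 1 list picked after its values were seen, stood at a median of 0.563 above the normal mean, against -0.081 to 0.096 in the model libraries. A mixture of 2 deposited libraries cannot be told apart either: the best pair with shares of 0.2 to 0.8, a range set after any share had been allowed, was model replicate 3 with normal replicate 3, where the middle of the genes spanned a share of 0.278, but model replicate 1 met the same criterion with the same pair (0.260). An animal that responded less, or received less, stays open and was not tested.

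Normal replicate 3 lay between normal replicates 1 and 2 at 53% of all tested genes and in 39 of 46 gene lists, against at most 44.2% of genes and 22 lists for any model or nanozyme library within its group. At the genes that differed at least 2-fold between normal replicates 1 and 2, it lay between them at 85.8%. That value is not extreme, since in the 80 other trios of libraries described below it reached 89.7%, with a median of 73.0%. If the RNA or reads of normal replicate 3 were a mixture of normal replicates 1 and 2, the mixing share would be alike at all genes. Within 0.1 of the median share (0.54) lay 48.9% of genes, against at most 40.6% in 80 other trios of libraries with a median share of 0.2 to 0.8, a limit set after the result because trios near 0 or 1 saturate. At genes of at least 50 FPKM, also added later, the value was 53.8% over 26 genes, against at most 29.0% in 3 such trios within the other groups. A mixture meets both values and stays a candidate explanation, while a mouse of intermediate expression cannot be told apart from it, since 3 trios from other groups are too few to set the range for normal mice. If it were a mixture, the SDs of normal lung and the shares of genes without overlap would rest on fewer than 3 mice. The counts without normal replicate 3 would then apply: 1916 higher and 1920 lower for model vs normal, and 600 and 148 for nanozyme vs normal.

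Ciliated, endothelial and resident fibroblast markers were lower in model than in normal lung. These calls did not rest on the deposited FPKM scaling alone. Of 54 members, 34 were called lower with the deposited values and at least 27 under each of 4 other scalings. All 4 rescale the same values and hold a total, a median ratio or the distribution alike between libraries. They therefore cannot exclude that a changed composition of the RNA shifted these values. Without normal replicate 3 fewer were called lower with the deposited values: 11 ciliated, 4 resident fibroblast and 2 endothelial genes. Dilution by infiltrating immune cells alone would lower each type alike, and the level of ciliated markers minus that of alveolar type 2 markers was lower in model than in normal lung by a difference of -1.07, but per library it ran from -1.92 to -0.29 against -0.64 to 0.59 (n = 3 mice each), which overlap. This pair of lists therefore cannot tell dilution from a difference between cell types in model lung. In nanozyme lung, which is not part of this pattern, the value ran from -1.55 to -1.18, below the normal range. Relative to the normal mean, ciliated medians ran from -2.17 to -1.36 over the model libraries, transitional epithelium medians from 0.15 to 0.90 and mesothelial medians from -0.075 to 1.15. The last 2 ranges overlapped those of the normal libraries, which were -0.146 to 0.193 and -0.281 to 0.180. The transitional epithelium list may also hold genes that other lung cell types express. These lists were picked after their values were seen, so they cannot test equal dilution of every structural type. Whether dilution lowered the ciliated, endothelial and fibroblast markers is not decided by them. A loss of cells, lower expression per cell and a different piece of lung stay open and were not tested.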
